A study of Gallus gallus with 2 samples.

How the data were processed

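RNA was sequenced from hearts of chicken embryos, with 1 pool of 10 hearts for the vehicle control and 1 pool of 10 for spermine NONOate at 10 µM, per the labels' protocols. Total RNA was extracted with Trizol and libraries were made with standard Illumina protocols, per the labels; whether RNA was selected by poly(A) tail, and whether strand was kept, is not given in the sources used here. Sequencing used an Illumina HiSeq instrument, per the series design text. Reads were aligned with STAR 2.4.2a to galGal4 with Ensembl release 81, and expression was estimated with Cufflinks 2.2.1, per the same text; the submitters' processing notes also name bcl2fastq and Cuffdiff. The deposited files hold the authors' FPKM values from Cufflinks, with lower and upper bounds of their 95% intervals, for 17108 annotated genes per library, all marked as quantified without error in both. No scaling between the libraries beyond FPKM is recorded, and the FPKM summed to 487268 in the control library and 536333 in the NO library. Because FPKM is a share of the library, a few abundant genes that differ can shift all others. The 20 most abundant genes held 20.8% of the summed FPKM in the control library and 28.6% in the NO library.

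Depth was read from the interval widths. A Cufflinks interval reaches 2 SD on each side, so the squared ratio of FPKM to that SD estimates the fragments behind a gene where only counting error enters. Among genes with under 5 such implied fragments, 1133 of 1214 (93.3%) in the control library and 1095 of 1167 (93.8%) in the NO library lay within 0.02 of a whole number. The implied fragments summed to 18262183 and 28802333, which are underestimates, since intervals of many abundant genes with several transcripts are wider than counting error. Over 1194 genes with whole values under 20 in both libraries, 1 fragment was worth 1.63 times more FPKM in the control library (median), so this was the shallower library. The median measured gene had 716 implied fragments in the control library and 977 in the NO library. Intervals cover estimation within 1 library only.

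Rows were joined by Ensembl identifier, and rows with the same symbol were summed, which left 16737 genes. Of the rows, 13736 carry a symbol and 3372 do not; 133 symbols stand on more than 1 row, 20 symbols are dates and 3 are bare numbers. Symbols are those of the deposited files. A RefSeq table of another assembly held the symbols of 11359 rows and none of the Ensembl identifiers (0 matched), so no coordinates were taken from it. Positions are those of the deposited files in galGal4, counted from 1; 8 of 8 mitochondrial coding genes checked had a length divisible by 3 on that reading. Genes with a mean of at least 1 FPKM over both libraries were kept (10824), and the log2 ratio of FPKM + 1 was taken, NO over control. Intervals of the log2 ratio combine both deposited intervals at the 95% level. With 1 library per group there is no test, no p-value and no SD over replicates, and genes were counted by size, at least 2-fold higher or lower.

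Before the data were examined, 33 gene lists were fixed, covering heart cells, other embryonic tissues, blood, signalling pathways, stress responses and metabolism. Outside the mitochondrial genes, members were matched by exact symbol. Members that the files spell otherwise were therefore missed, such as PAX6 (Pax-6), BMP10 (BMP-10) and SLC8A1 (NCX1). A list needed 5 measured members, which 32 had. Its median log2 difference was set against the medians of 10000 random lists of the same size, matched in 20 bins of mean expression (seed 20160), and it stood apart when it lay outside the central 95%. The percentile describes these libraries and does not test the treatment. Some genes belong to more than 1 list: 3 measured members of the neural list, 4 of the somite list and 2 of the endoderm list are also in others. CDH2 and NCAM1 of the neural list and MYL1, TNNC2 and ACTA1 of the somite list are also expressed by embryonic heart muscle. Members were counted when at least 1.5-fold higher or lower. The genes named were also chosen by a rule fixed before: the 10 largest differences in each direction among genes with a symbol and at least 5 FPKM in the higher library, up to 4 members with the largest differences from each list, and 26 genes whatever their values. Of the 26, HAND2, MYH6, MYH15 and NOS2 were not matched to a symbol and are not analysed here. Some genes that the rule selects are not reported here. A version of the first part limited to genes with at least 50 implied fragments was added after the data were seen.

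The counts and lists were tested on simulated libraries with 10899 genes drawn from the real means. Of 50 genes set 4-fold higher, 50 were called, and of 50 set 4-fold lower, 49. Of those set 2.5-fold higher 43 of 50 were called, and of those set 2.5-fold lower 34 of 50. Among 10669 unchanged genes 23 were called, and 2 of 100 lists of unchanged genes stood apart. The simulated libraries held counting error and small independent noise per gene. They held no variation between pools and no unchanged genes that move together, so these counts are not error rates for this comparison. Alternatives covered the scaling, the pseudocount, the filter on low values, the treatment of repeated symbols, the fold threshold, the deposited intervals, the matching of random lists, shared members and the mean in place of the median. Added after the data were seen were the limits on implied fragments, the removal of features under 200 bases and the centring by chromosome size (chromosomes 1 to 5, 6 to 10, 11 and above, Z, W, mitochondrial and unplaced). The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.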

Results

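Gene expression was measured by RNA sequencing in hearts of chicken (Gallus gallus) embryos treated in the egg with a nitric oxide (NO) donor or with its vehicle. Spermine NONOate is a compound that releases NO and leaves spermine, a polyamine. Eggs received 20 µl of spermine NONOate at 10 µM or of phosphate-buffered saline through the air sac after 24 h at 37 °C. Hearts were taken at 45 h, which the labels do not clearly count from the start of incubation or from the injection. Each group was 1 pool of 10 hearts and 1 library, called the control library and the NO library here. The deposited values were FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library) for 17108 annotated genes, each with a 95% interval. Read depth was recovered in part from the widths of these intervals, as a sum of at least 18262183 fragments in the control library and 28802333 in the NO library. Each interval covers the estimation of 1 library and not the difference between pools, and no difference here has a replicate check.

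The design poses 1 question, how expression in the embryonic heart differs after exposure to the NO donor. Neither group received spermine alone, so NO cannot be told apart from the spermine that the donor leaves. Genes of the contractile apparatus, calcium handling, haemoglobin and mitochondria were higher in the NO library. Markers of neural tissue, neural crest, endoderm and somites, a joint list of retinoic acid and Hox genes, and Wnt pathway genes were lower. The median of the 30 measured sarcomere genes was 5.01-fold higher, and that of the 21 measured endoderm and foregut genes was 3.57-fold lower. The list of NO and cGMP signalling, which also holds genes of NO synthesis, had a median log2 difference of −0.16 and did not stand apart. Of its 25 measured members, 6 were at least 1.5-fold higher and 4 at least 1.5-fold lower. The NO receptor subunits GUCY1A3 and GUCY1B3 had log2 differences of 0.61 and 0.88.

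Of 10824 genes with a mean of at least 1 FPKM, 395 (3.65%) were at least 2-fold higher in the NO library and 1115 (10.3%) at least 2-fold lower. Differences are log2 ratios of FPKM + 1, NO over control, which understate the difference of genes with low values. The deposited intervals did not overlap for 375 of the 395 genes and 1089 of the 1115. Among all 10824 genes they did not overlap for 7678 (70.9%), so intervals apart do little to set the 2-fold genes off. Across genes, which are not independent replicates, Pearson's r of the log2 values was 0.92 and Spearman's rho was 0.90. The median gene lay at −0.11, and the differences given here are not shifted by that amount. Genes at least 2-fold higher were 26.2% of all such genes as deposited, and numbered 514 against 885 lower (36.7%) after a trimmed mean scaling, 528 against 883 (37.4%) after upper quartile scaling and 509 against 784 (39.4%) when each gene was set against its chromosome size class. The last of these was chosen after the data were seen. Rescaling without the erythroid, mitochondrial and 20 most abundant genes gave 407 against 1093 (27.1%), close to the counts as deposited. Genes at 5 FPKM or more in the control library and under 1 FPKM in the NO library numbered 56, against 14 with the opposite pattern.

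**Figure D1:**
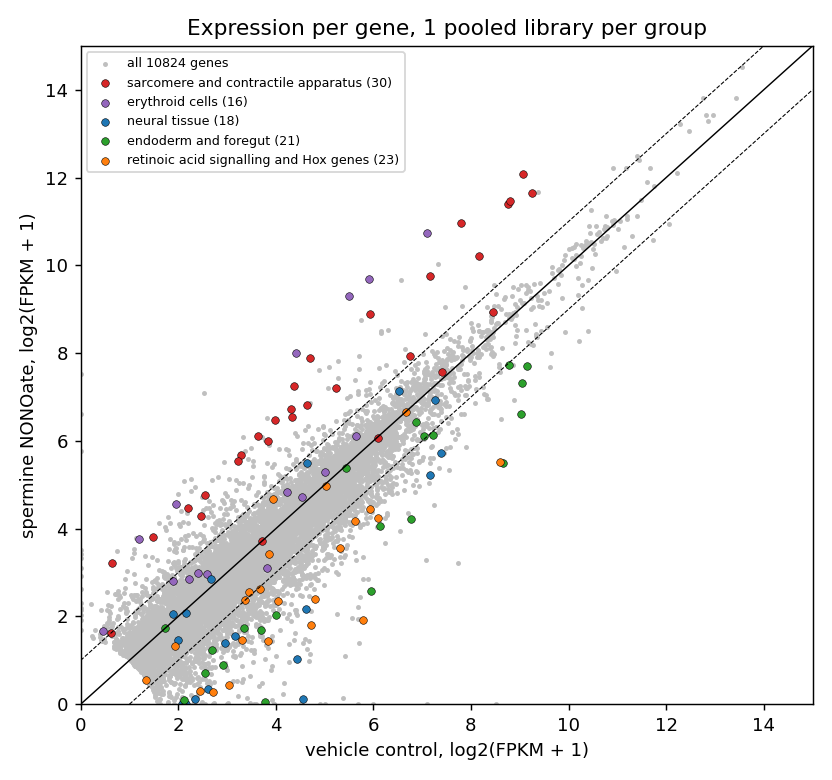
Expression of 10824 genes, with log2(FPKM + 1) in the control library on the x axis and in the NO library on the y axis; each point is 1 gene, coloured points mark gene lists, the solid line marks equal values and the dashed lines 2-fold differences. Most sarcomere and erythroid genes lie above the solid line, and most neural, endoderm and retinoic acid or Hox genes lie below it.

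Contractile genes were higher together. Of the sarcomere list, 26 of 30 measured members were at least 1.5-fold higher and 0 at least 1.5-fold lower, with a median log2 difference of 2.33. MYL2, the regulatory myosin light chain of the ventricle (ENSGALG00000004582, chromosome 15, 6028493 to 6032632 in galGal4), was at 535 FPKM (95% interval 526 to 545) in the control library and 4343 FPKM (4321 to 4364) in the NO library. MYL3, an essential myosin light chain (ENSGALG00000005448, chromosome 2, 3420143 to 3455225), was 9.02-fold higher, and MYBPC3, cardiac myosin-binding protein C (ENSGALG00000008148, chromosome 5, 22280278 to 22337792), was 9.02-fold higher. CSRP3, a LIM protein of the Z-disc, was 7.85-fold higher. Cardiac troponin T (TNNT2) was at 604 and 3189 FPKM, in control and NO libraries in that order, cardiac actin (ACTC1) at 448 and 2834 FPKM and MYH7, a slow myosin heavy chain, at 8.83 and 49.99 FPKM. No random list of the same size and expression, among 10000, had a median as high, and the central 95% of random medians ran from −0.25 to 0.18. In the same libraries the neural tissue list had a median of −1.63 and the endoderm list one of −1.84.

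Calcium handling, ion channel and gap junction genes were also higher, though less evenly. Of this list, 14 of 26 measured members were at least 1.5-fold higher and 2 at least 1.5-fold lower, with a median of 0.61, above all 10000 random lists. PLN, phospholamban, the inhibitor of the sarcoplasmic calcium pump (ENSGALG00000027583, chromosome 3, 62380777 to 62388473), was at 4.77 FPKM (95% interval 3.91 to 5.62) in the control library and 136 FPKM (132 to 139) in the NO library, which is 23.7-fold higher. GJA5, connexin 40, was 5.30-fold higher, CASQ2, the calcium store protein calsequestrin 2, was 4.70-fold higher and CACNA2D1, a calcium channel subunit, was 3.35-fold higher. The median of the neural tissue list was −1.63 in these libraries.

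Cardiac transcription factors did not stand apart as a group, and individual members differed in both directions. Their median was 0.01 and their mean −0.08, at a percentile of 81.3 among random lists; 8 of 31 measured members were at least 1.5-fold higher and 10 at least 1.5-fold lower. IRX4, a ventricular factor, had a log2 difference of 1.67 (1.54 to 1.81), while FOXC2, IRX1 and SALL1 had −1.83 (−1.98 to −1.69), −1.75 (−1.88 to −1.62) and −1.57 (−1.64 to −1.50). Among genes fixed for report whatever their values, NKX2-5 was at 79.99 and 95.2 FPKM, ISL1 at 7.86 and 9.44 FPKM, GATA4 at 16.3 and 32.2 FPKM, TBX5 at 14.5 and 26.9 FPKM, TBX20 at 15.5 and 36.7 FPKM and MEF2C at 6.74 and 16.1 FPKM. TBX20 was 2.29-fold higher and MEF2C 2.21-fold higher. Without the members that another list also holds, the list's percentile was 98.1.

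The 5 measured haemoglobin genes were at least 6.02-fold higher in the NO library. HBE was at 44.03 FPKM (95% interval 41.6 to 46.4) in the control library and 629 FPKM (623 to 636) in the NO library. HBAA was 13.6-fold higher, HBG1 12.3-fold higher and HBAD 12.02-fold higher; reads of near-identical globin genes can be shared, so the split among them is uncertain. Of the erythroid list as a whole, 11 of 16 measured members were at least 1.5-fold higher and 1 at least 1.5-fold lower, with a median of 0.78, above all 10000 random lists. The list of leukocyte and thrombocyte genes, with 6 measured members, had a median of 0.48 and a percentile of 99.6. GP1BB and GP9, platelet glycoproteins found on thrombocytes, had log2 differences of 0.85 (0.60 to 1.09) and 0.59 (0.21 to 0.98), LCP1, a leukocyte actin-bundling protein, 0.59 (0.41 to 0.76), and ITGB3 −0.46 (−0.53 to −0.39). This small list no longer stood apart when its mean replaced its median or when it was matched on control expression, at a percentile of 96.4 at lowest. In the same libraries the medians of the sarcomere, neural and endoderm lists were 2.33, −1.63 and −1.84.

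Transcripts of the respiratory chain were higher from both genomes. Of the mitochondrially encoded genes, 8 of 12 were at least 1.5-fold higher and 0 lower, with a median of 0.86, above all 10000 random lists. ND4L was 2.46-fold higher, ND4 2.14-fold higher and ND2 2.06-fold higher, and COX1 was at 12049 and 23545 FPKM. Mitochondrial genes made up 16.3% of the summed FPKM in the control library and 24.6% in the NO library. Of the nuclear-encoded oxidative phosphorylation genes, 20 of 54 measured members were at least 1.5-fold higher and 4 at least 1.5-fold lower, with a median of 0.47, also above all 10000 random lists. NDUFA5 was 2.63-fold higher, COX7A2 2.25-fold higher and NDUFS6 2.20-fold higher, whereas NDUFAB1 was 2.14-fold lower. Set against the median of their own genome, the mitochondrial genes did not stand apart, as that setting removes their common shift by construction. In the same libraries the sarcomere list was at 2.33, the neural list at −1.63 and the endoderm list at −1.84.

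**Figure D2:**
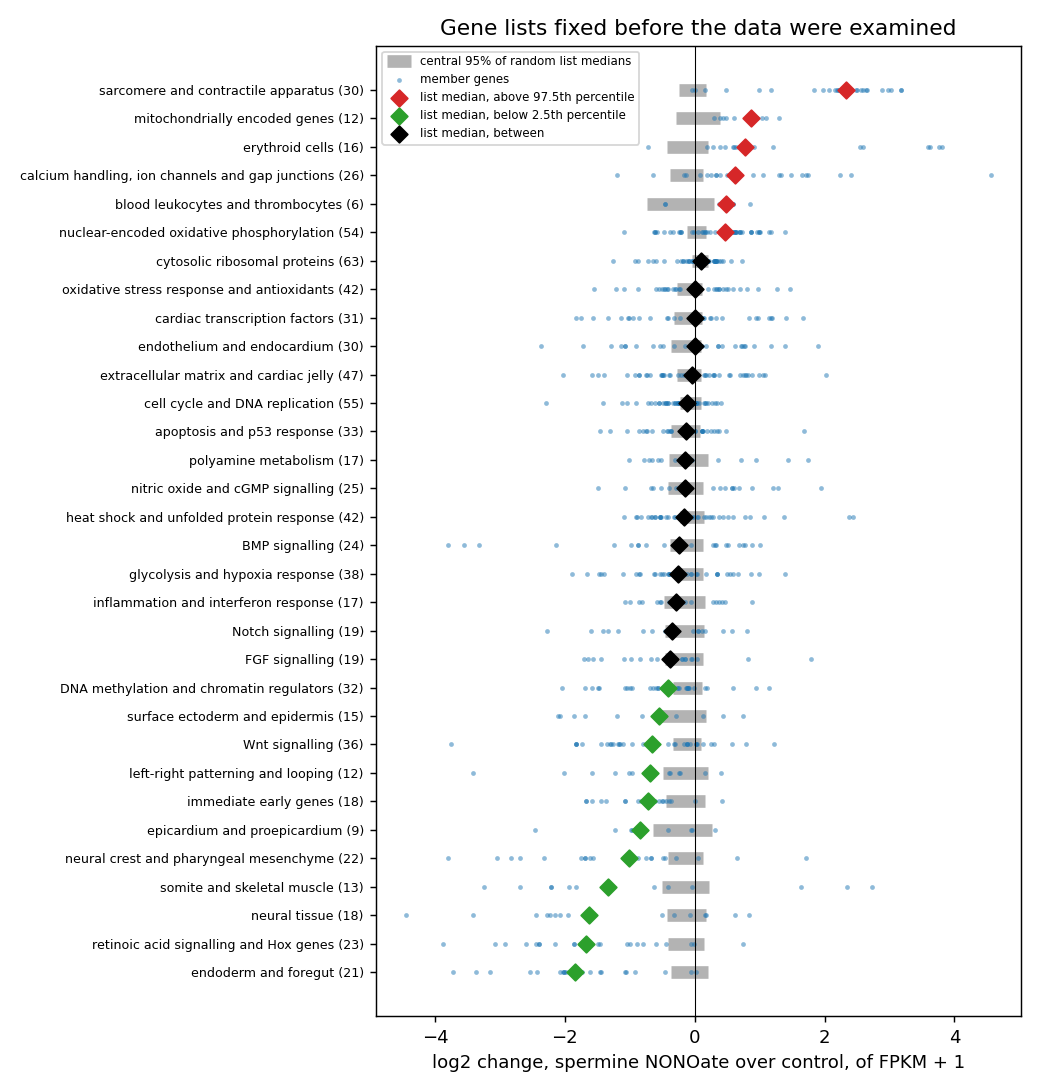
Log2 difference of FPKM + 1, NO over control, on the x axis for the 32 gene lists with at least 5 measured members, with the number of members in brackets; small points are genes, diamonds are list medians and grey bars hold the central 95% of medians of 10000 random lists. The sarcomere list has the highest median, 2.33, and the endoderm list the lowest, −1.84.

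Markers of tissues outside the heart were lower in the NO library. Of the neural tissue list, 2 of 18 measured members were at least 1.5-fold higher and 11 at least 1.5-fold lower, with a median of −1.63. EN2, a factor of the midbrain and hindbrain (ENSGALG00000023430, chromosome 2, 7875412 to 7877529), was at 22.7 FPKM (95% interval 20.1 to 25.3) in the control library and 0.0844 FPKM (0 to 0.204) in the NO library. SOX2, a factor of neural progenitors, was 5.46-fold lower and HES5, a Notch target, 4.83-fold lower. Of the endoderm and foregut list, 0 of 21 measured members were at least 1.5-fold higher and 18 at least 1.5-fold lower, with a median of −1.84. CDX2, a factor of the caudal embryo and hindgut, was at 12.8 and 0.0433 FPKM, a log2 difference of −3.72 (−3.96 to −3.49) with 1 implied fragment in the NO library. The secreted carriers RBP4, TTR and TF (retinol-binding protein, transthyretin and transferrin) were 10.3-fold lower, 8.87-fold lower and 5.80-fold lower. Both lists lay below all 10000 random lists, in libraries where the sarcomere median was 2.33.

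Neural crest and somite markers followed the same direction. Of the neural crest and pharyngeal mesenchyme list, 2 of 22 measured members were at least 1.5-fold higher and 16 at least 1.5-fold lower, with a median of −1.01, below all random lists. MSX1 (ENSGALG00000015013, chromosome 4, 78388177 to 78390740) was at 134 FPKM (95% interval 129.8 to 139) in the control library and 8.71 FPKM (7.83 to 9.58) in the NO library. SOX10 was 8.28-fold lower, SOX8 7.08-fold lower and PAX3 6.46-fold lower. Of the somite and skeletal muscle list, 3 of 13 measured members were at least 1.5-fold higher and 8 at least 1.5-fold lower, with a median of −1.33, again below all random lists. Over 14 alternatives the value of the somite list ran from −1.385 to −0.553, and its percentile reached 1.745 at highest. TCF15, a somite factor, was 9.46-fold lower, but MYL1 and TNNC2, muscle genes of that list, were 6.64-fold higher and 5.09-fold higher. Epicardial and proepicardial markers had a median of −0.84 (percentile 0.57), with 5 of 9 at least 1.5-fold lower and 0 higher. UPK3B was at 4.50 FPKM in the control library and listed at 0 in the NO library, BNC1 was 2.33-fold lower, SEMA3D 1.98-fold lower and LRP2 1.94-fold lower. Surface ectoderm markers had a median of −0.55 (percentile 1.80); 1 of 15 measured members were at least 1.5-fold higher and 7 at least 1.5-fold lower. DLX3 was 4.29-fold lower, TFAP2C 4.21-fold lower, KRT14 3.64-fold lower and GATA2 3.22-fold lower. With a pseudocount of 5, the epicardial and ectoderm lists no longer stood apart, at percentiles of 2.64 and 5.09, nor did the epicardial list among its 8 members with 100 implied fragments in the control library, at 3.50.

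Retinoic acid and Hox genes, which pattern the embryo's axis, were lower as a group. Of this list, 1 of 23 measured members were at least 1.5-fold higher and 19 at least 1.5-fold lower, with a median of −1.68, below all random lists. CRABP2, a retinoic acid binding protein (ENSGALG00000029140, chromosome 25, 468703 to 470859), was at 384 FPKM (95% interval 368 to 399) in the control library and 44.7 FPKM (40.5 to 48.8) in the NO library, which is 8.43-fold lower. HOXB4 was 7.57-fold lower and HOXB6 6.08-fold lower. Wnt pathway genes had a median of −0.66, below all random lists; 2 of 36 measured members were at least 1.5-fold higher and 19 at least 1.5-fold lower. WNT4 was 13.4-fold lower, the receptor FZD7 3.55-fold lower, TCF7L1 3.55-fold lower and AXIN2, a target of the pathway, 3.54-fold lower. The left-right patterning and looping list had a median of −0.68 (percentile 0.25), with 6 of 12 at least 1.5-fold lower and 0 higher. SHH was 4.02-fold lower, VANGL2 2.99-fold lower and ACVR2B 2.35-fold lower. Without the members that another list also holds, this list's percentile was 14.7 and it no longer stood apart. These values stand beside medians of −1.63 for neural tissue, −1.84 for endoderm and 2.33 for the sarcomere.

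Other signalling lists did not stand apart, although single members differed widely. BMP genes had a median of −0.24 (percentile 13.7); 5 of 24 measured members were at least 1.5-fold higher and 9 at least 1.5-fold lower. CHRD and FST, secreted antagonists of the pathway, were 11.7-fold lower and 9.96-fold lower, NBL1 was 4.39-fold lower, and BMP4 was at 20.2 and 10.5 FPKM. FGF genes had a median of −0.39 (percentile 6.17); 2 of 19 measured members were at least 1.5-fold higher and 8 at least 1.5-fold lower. FGFR3 was 3.25-fold lower, FGF3 3.14-fold lower, FGFR2 2.97-fold lower and FGF13 3.47-fold higher. Notch genes had a median of −0.36 (percentile 7.61); 1 of 19 measured members were at least 1.5-fold higher and 7 at least 1.5-fold lower. Besides HES5, DLL1 was 3.04-fold lower, NRARP 2.67-fold lower and LFNG 2.52-fold lower. Each of these 3 lists lay below the 2.5th percentile in at least 1 alternative, at 0.81, 0.72 and 2.31 at lowest. At highest their percentiles were 92.5, 13.7 and 71.1, and the value of the BMP list ran from −0.54 to 0.13.

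Genes of NO and cGMP signalling differed in both directions. Of the list, 6 of 25 measured members were at least 1.5-fold higher and 4 at least 1.5-fold lower; its median was −0.16 and its mean 0.10, which differ in sign, at a percentile of 32.5. NPPB, a natriuretic peptide that acts through cGMP (ENSGALG00000004574, chromosome 21, 5577062 to 5579681), was at 50.98 FPKM (95% interval 47.9 to 54.1) in the control library and 199 FPKM (195 to 204) in the NO library. ASS1, an enzyme that regenerates arginine for NO synthesis, was 2.79-fold lower, MRVI1, a target of cGMP-dependent kinase, 2.45-fold higher and the phosphodiesterase PDE3A 2.30-fold higher. The subunits of soluble guanylate cyclase, the NO receptor, were at 1.71 and 3.14 FPKM for GUCY1A3 and 2.32 and 5.13 FPKM for GUCY1B3, with log2 differences of 0.61 (0.49 to 0.73) and 0.88 (0.70 to 1.07). PRKG1, cGMP-dependent protein kinase, had 0.68 (0.62 to 0.75). Endothelial NO synthase (NOS3) was at 6.83 and 4.001 FPKM, −0.65 (−0.92 to −0.37) on the log2 scale, and NOS1 was under 1 FPKM in both libraries. In these libraries the sarcomere list was at 2.33 and the neural list at −1.63.

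Polyamine genes, listed because the compound leaves spermine, did not stand apart. Their median was −0.15 and their mean 0.01, at a percentile of 25.5; 4 of 17 measured members were at least 1.5-fold higher and 4 at least 1.5-fold lower. AZIN2 was 3.36-fold higher, ATP13A3 2.70-fold higher and ATP13A2 2.01-fold lower. Spermine oxidase (SMOX) had a log2 difference of 0.94 (0.78 to 1.10), spermidine/spermine acetyltransferase (SAT1) −0.66 (−0.79 to −0.53) and ornithine decarboxylase (ODC1) −0.56 (−0.60 to −0.53). Antioxidant genes had a median of 0.01 and a mean of 0.00 (percentile 77.4); 6 of 42 measured members were at least 1.5-fold higher and 5 at least 1.5-fold lower. The metallothionein MT4 was 2.92-fold lower and GPX1 2.33-fold lower, while the extracellular superoxide dismutase SOD3 was 2.77-fold higher and MGST3 2.41-fold higher. HMOX1, a gene induced by oxidative stress, was at 9.55 and 10.2 FPKM, with a log2 difference of 0.08 (−0.07 to 0.24).

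**Figure D3:**
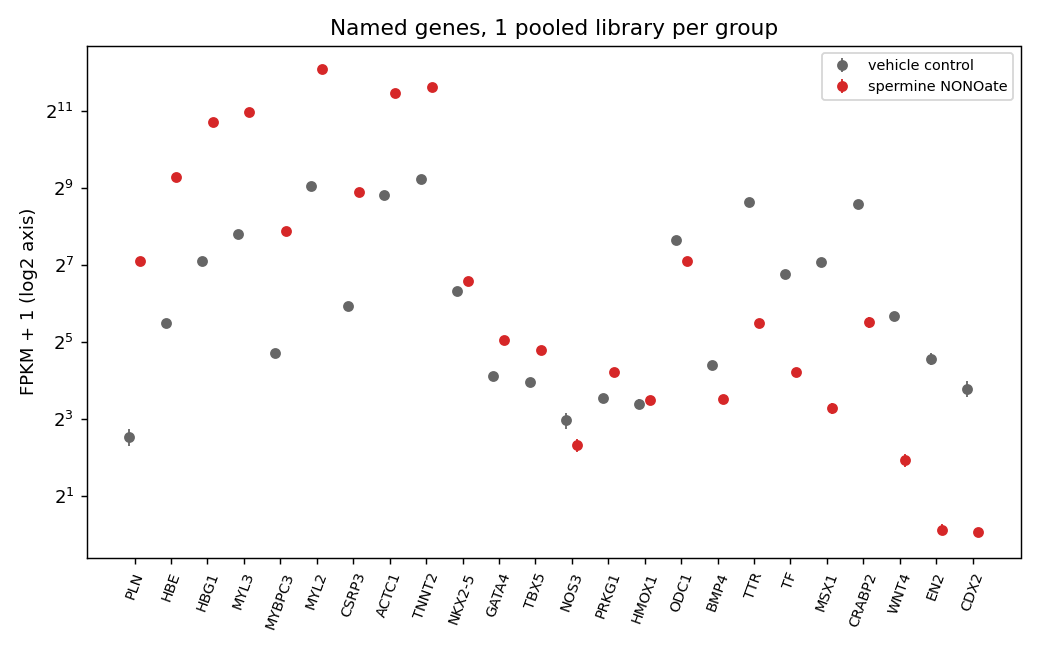
FPKM + 1 on a log2 axis for 24 named genes in the control library (grey) and the NO library (red), with the deposited 95% intervals; each group has 1 library, so the bars do not show variation between pools. MYL2 has the highest value shown in the NO library, and EN2 and CDX2 lie near 0 FPKM there.

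Immediate early genes and chromatin regulators were lower as groups. Immediate early genes had a median of −0.72 (percentile 0.06), with 10 of 18 at least 1.5-fold lower and 0 higher. FOS and FOSL2 were both 3.20-fold lower, JUN 2.98-fold lower and MYCN 2.72-fold lower. Chromatin regulators had a median of −0.41 (percentile 0.64); 3 of 32 measured members were at least 1.5-fold higher and 12 at least 1.5-fold lower. The DNA methyltransferases DNMT1, DNMT3A and DNMT3B were 3.22-fold lower, 2.999-fold lower and 2.81-fold lower, and SMARCA4 was 4.12-fold lower. SMARCA4 and DNMT1 lie on unplaced scaffolds, whose 501 measured genes had a median of −0.67. Of the genes named in other paragraphs, FOXC2, TCF7L1, COL2A1, HK2, CALR and GADD45B, all lower, also lie on such scaffolds. So do HBAA and HBAD, which were higher. Against the median of its chromosome size class, the chromatin list had a percentile of 2.83 and no longer stood apart. In these libraries the medians of the sarcomere, neural and endoderm lists were 2.33, −1.63 and −1.84.

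Endothelial and endocardial genes did not stand apart (median 0.01, mean −0.04, percentile 87.3); 9 of 30 measured members were at least 1.5-fold higher and 8 at least 1.5-fold lower. NRP2 was 5.15-fold lower and LMO2 3.30-fold lower, whereas NFATC1, an endocardial factor, was 3.71-fold higher and PECAM1 2.61-fold higher. KDR, a VEGF receptor, was at 11.8 and 20.7 FPKM and VEGFA at 9.86 and 6.07 FPKM. Among genes with a mean of at least 10 FPKM this list had a percentile of 99.5. Matrix genes had a median of −0.04 (percentile 66.9); 10 of 47 measured members were at least 1.5-fold higher and 11 at least 1.5-fold lower. The fibrillar collagens COL3A1, COL2A1 and COL1A2 were 4.08-fold lower, 3.005-fold lower and 2.79-fold lower, LOX, which cross-links collagen, was 4.06-fold higher, and HAS2, the hyaluronan synthase of the cardiac jelly, was at 21.2 and 24.8 FPKM.

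Glycolysis and hypoxia genes had a median of −0.26 at a percentile of 2.78, just inside the range of random lists; 4 of 38 measured members were at least 1.5-fold higher and 11 at least 1.5-fold lower. HK2 was 3.70-fold lower, NDRG1 3.15-fold lower and PKM 2.71-fold lower; with a pseudocount of 0.1 or only members with 100 implied fragments in the control library, the list stood apart, at 1.56 at lowest. Heat shock and unfolded protein genes had a median of −0.16 and a mean of 0.00 (percentile 9.08); 7 of 42 measured members were at least 1.5-fold higher and 9 at least 1.5-fold lower. The small heat shock proteins HSPB7, HSPB2 and HSPB1, which are abundant in muscle, were 5.40-fold higher, 5.21-fold higher and 2.60-fold higher, and the chaperone CALR was 2.13-fold lower. Cell cycle genes had a median of −0.12 (percentile 20.9), with 8 of 55 at least 1.5-fold lower and 0 higher. The replication licensing genes CDC6, CDT1 and MCM5 were 4.90-fold lower, 2.67-fold lower and 2.17-fold lower, and CDC25A 2.07-fold lower.

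Apoptosis and p53 genes had a median of −0.13 (percentile 44.7); 1 of 33 measured members were at least 1.5-fold higher and 8 at least 1.5-fold lower. BOK was 3.22-fold higher, and SESN2, MCL1 and GADD45B were 2.75-fold lower, 2.48-fold lower and 2.06-fold lower. Inflammation and interferon genes had a median of −0.28 (percentile 19.2); 1 of 17 measured members were at least 1.5-fold higher and 4 at least 1.5-fold lower. NFKB2 was 2.10-fold lower, CD40 1.99-fold lower, TAP2 1.81-fold lower and IFI27L2 1.84-fold higher. Cytosolic ribosomal proteins had a median of 0.10 (percentile 54.4); 1 of 63 measured members were at least 1.5-fold higher and 6 at least 1.5-fold lower. RPLP0, RPS28 and RPL12 were 2.38-fold lower, 1.89-fold lower and 1.83-fold lower, and RPS16 was 1.65-fold higher. Only 2 replication-dependent histone genes were measured, too few for a value. In all, 6 of 32 lists lay above the central 95% of random medians, 11 below and 15 within. Lists of unrelated genes would put 1.6 outside. Genes of a tissue or pathway move together, and some are on several lists, so this comparison is not a test.

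The 20 largest differences among genes with symbols, 10 in each direction, held 12 features shorter than 200 bases, such as microRNA genes, all with 0 to 10 implied fragments in each library. The gene of let-7i, for example, was listed at 364 FPKM (95% interval 0 to 1093) on 1 implied fragment in the control library and at 0 in the NO library. The others of the 20 were EN2, FOXD1 and RNase_MRP among the lowest and PLN, HBE, HBAA, HBG1 and HBAD among the highest. FOXD1 (ENSGALG00000012644, chromosome Z, 24613985 to 24614464) was at 50.9 FPKM (95% interval 45.7 to 56.04) in the control library and 1.61 FPKM (0.924 to 2.30) in the NO library. With at least 50 implied fragments required in the library with more, a rule added after the data were seen, the lowest 10 also included Pax-6, MSX1, WNT4, CDX2, CHRD and SPP1. The highest 10 then also held MYL3, MYBPC3, FKBP1B, MYL2 and CSRP3. FKBP1B, which binds the ryanodine receptor, was 8.48-fold higher, Pax-6 14.01-fold lower and SPP1, osteopontin, 10.97-fold lower.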

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

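The limits on implied fragments, the removal of features under 200 bases and the centring by chromosome size were chosen after the data were seen. Leaving out a library was impossible, since each group has 1. No paired analysis was possible because each group has 1 library and no test was run. The 395 genes higher and 1115 lower became 201 and 484 with a pseudocount of 5, 210 and 516 with a mean of at least 10 FPKM, 1038 and 2420 at 1.5-fold, and 94 and 160 at 4-fold, in each case by construction, since these settings shrink ratios, test fewer genes or move the threshold. Pearson's r across genes was 0.86 with a mean of at least 10 FPKM. Under the other settings both counts stayed within 1.5 times the reported ones; median-centring gave 503 and 899 (35.9% higher). The median of the sarcomere list ran from 2.00 to 2.47, that of neural tissue from −1.98 to −0.79 and that of endoderm from −2.14 to −1.04 over 14 alternatives each, and all 3 stood apart in every one. The NO and cGMP list stood apart in none of 14, with values from −0.16 to 0.10. The percentile of this list ran from 16.1 to 96.1, so at highest it lay close to the upper limit. Of 32 lists, 20 kept their call in every alternative that gave a value and 12 changed in at least 1. Median-centring and the trimmed mean shift all genes alike, so they leave the percentiles unchanged by construction. Of 132 named genes at least 2-fold apart, 0 reversed in sign over 7 alternatives. That result was nearly fixed in advance, since the rescalings shifted genes only slightly and a pseudocount cannot change a sign. For let-7i, a feature under 200 bases, 1 fragment was worth 364 FPKM.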

Other observations

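The tests of tissue content, dilution, fragments not scaled for depth, heart-cell response, blood and shared globin reads given here were chosen after the result was seen. Those of base composition, depth limits and the W chromosome were chosen after a first look at the data but before the value each measures was seen; the depth limits and the spread of the sarcomere list were then dropped and taken up again when other values were known. The genes in this paragraph and the next were picked after their values were seen, so they stand for no group. BMP-10 and NCX1 belong to the fixed BMP and calcium handling lists as BMP10 and SLC8A1. Their symbols were not matched, so the values of those lists leave them out. POUV, a pluripotency factor of the early chick embryo, was 8.62-fold lower, and OLIG3, a factor of the dorsal neural tube, was at 10.02 and 0.0259 FPKM in control and NO libraries. GBX2, of the hindbrain, was 5.90-fold lower and SP5, a Wnt target, 5.44-fold lower. BMP-10, a growth factor of trabecular muscle, was 7.36-fold higher, VCAM1 6.98-fold higher, NCX1, the sodium-calcium exchanger, 4.36-fold higher, POPDC2 4.72-fold higher, BVES 4.10-fold higher and RBM24, a muscle splicing factor, 4.63-fold higher. The endothelin gene EDN1 was 2.98-fold higher, RCAN1, a calcineurin target, 2.94-fold higher and myoglobin (MB) 3.69-fold higher.

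Non-coding RNAs that lack a poly(A) tail were looked up, and 9 were found, while RNase_P was not matched to a symbol. Of the 9, 5 had a mean of at least 1 FPKM, and 4 of these were lower in the NO library. RNase_MRP had a log2 difference of −3.92 (−4.47 to −3.37), 7SK of −2.00 (−2.26 to −1.74), U3 of −2.60 (−3.03 to −2.18) and 5_8S_rRNA of −2.71 (−3.31 to −2.10), while Metazoa_SRP had −0.12 (−0.66 to 0.42). Below that mean, U2 had 0.34 (−1.17 to 1.86) on 1 and 2 implied fragments, and 5S_rRNA, U1 and U6 were listed at 0 in both libraries. Genes on unplaced scaffolds had a median of −0.67 and those on chromosomes 11 and above −0.22, against −0.03 on chromosomes 1 to 5. No explanation was tested for these values.

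The first pattern is that contractile genes were higher and neural, somite and endoderm markers lower in the NO library. The gap between the sarcomere and neural medians kept 101% of its size (3.96 before and 4.01 after centring by chromosome size). Differences between chromosome size classes therefore do not account for the gap. Class medians ran only from −0.67 (unplaced) to 0.70 (mitochondrial), so centring could hardly have removed a gap of this size. Base composition of single genes was not measured, so a bias from it stays open. Of 52 members of the neural, somite and endoderm lists, 36 had fewer fragments in the deeper NO library, beyond their intervals, and 13 had more. Deeper sequencing alone would not lower fragment counts, which argues against depth for most members of these lists. The count restates that the lists were lower by more than the depth ratio of 1.63, so it is no separate check. Limits on implied fragments decide nothing: with at least 100 in the shallower library 100.8% of the gap was kept, but only 1 of 18 neural and 2 of 30 sarcomere genes were taken out, and with 100 in both libraries 71.7% was kept, but 7 neural genes were taken out, 5 of them under 1 FPKM in the NO library. Dilution by other tissue with the same heart expression in both pools would shift heart-restricted genes by 1 factor, and it stays open. The interquartile range over the whole sarcomere list was 0.59, under the bound of 1 set to exclude dilution. At most 7 of the 30 sarcomere genes had intervals that hold 1 factor, and 16 when each interval was widened by 0.25 on the log2 scale; the deposited intervals hold no variation between pools, and no heart-restricted subset was fixed, so neither value decides. MYBPC3 had a log2 difference of 3.17 (3.13 to 3.21), ACTC1 of 2.66 (2.65 to 2.67) and TNNT2 of 2.40 (2.31 to 2.48), and outside the list PLN had 4.57 (4.35 to 4.78). The cardiac factors fixed for report differed less, from 0.24 (0.09 to 0.38) for ISL1 to 1.19 (1.07 to 1.32) for TBX20. Whether these factors are restricted to the heart was not measured, so they do not decide either. Tissue from outside the heart in the control pool is a candidate explanation that no value here decides. Over the 3 lists, 6 members (HES5, EN2, PAX3, PAX2 and CDX2 among them) were at 5 FPKM or more in the control library and under 1 FPKM in the NO library and 0 had the opposite pattern, but this restates that the lists were lower, and over all genes the counts were 56 and 14; the abundant TTR was at 399.95 and 44.2 FPKM. A difference in RNA quality or selection between the libraries, which could also underlie the lower RNAs without a poly(A) tail, such as 7SK at −2.00 and U3 at −2.60, was not tested on these lists and stays open. The retinoic acid and Hox, Wnt and left-right lists, immediate early genes, chromatin regulators and respiratory chain genes are not separated from tissue content either. A response of heart cells to the donor, through NO or spermine, cannot be told apart from tissue content, or from any other difference between the pools, with 1 pool each. The NO and cGMP list was at a percentile of 32.5, and from 16.1 to 96.1 over the alternatives. The cardiac transcription factors were at the 81.3rd percentile, or the 98.1st without shared members.

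The second pattern is the higher level of haemoglobin genes. Reads shared among near-identical globin genes are argued against as the whole cause, since all 5 measured globin genes, on chromosome 1 and on a separate scaffold, were at least 4-fold higher. More blood in the NO pool may account for it but was not decided: 5 red-cell genes other than globins had a median log2 difference of 0.53, between the bounds of 0.5 and 1, and 3 of them had a mean under 1 FPKM. Among these, SLC4A1, the red-cell anion exchanger, was 5.86-fold higher and EPB42 2.30-fold higher, while HEMGN was at 0.89 and 0.92 FPKM. Whether exposure to the donor altered blood formation stays open and untested.

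The third pattern concerns the sex of the pooled embryos, as the W chromosome is carried by females. The median of 5 measured W-linked genes lay −0.14 from the median of all genes, with 2 genes higher and 3 lower. A difference in the share of females large enough to move W-linked genes together is therefore unlikely, though 5 genes bound a small one only loosely.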
